A study of Arabidopsis thaliana with 28 samples.

How the data were processed

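IPARE libraries hold the 5′ ends of RNA that an antibody against NRPE1, the largest subunit of RNA polymerase V (Pol V), pulled down, made by template switching, per the labels' protocols. The plants were Arabidopsis thaliana seedlings of 18 days. The 24 IPARE libraries come from 11 genotypes. Whole-genome bisulfite sequencing (WGBS) covered 4 leaf samples of 3.5-week-old Col-0 and nrpe1 plants. UMI-tools, cutadapt, Bowtie2, Bismark and the TAIR10 build are named, with no versions, in the submitters' processing notes. The role of each tool, the read filters and the treatment of reads with several mapping positions are not given in the sources used here.

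The authors deposited whole-number read counts in 794311 windows of 200 bp that start every 150 bp on chromosomes 1 to 5, so that neighbouring windows share 50 bp and can share reads. Only 6 windows have another length. The same deposited table holds the average methylation level per window as a fraction, and the 1 CHH column per genotype was read; CG and CHG levels were not used here. These levels are the authors' averages over the samples of a genotype, with no coverage, so depth is unknown and no interval, SD or test is given for them. They are printed as percentages. Further deposited lists divide the windows into 3 classes: transcribed by Pol V at targets of RNA-directed DNA methylation (RdDM), transcribed by Pol V elsewhere (non-RdDM), and not transcribed by Pol V. The lists are named for a hidden Markov model, whose settings are not given in the sources used here. The labels name them for the Col-0 and nrpe1 libraries of the untagged set, gp3 and gp4, so class values in those libraries are not independent of the classes.

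Samples were grouped by the genotype in their labels. Titles also carry a tag (none, gp2, gp3, gp4, gp5 or gp6), called a set here, whose meaning the labels do not state. The Col-0 libraries of the untagged set and of gp2 are both numbered replicate 1. Every set holds a Col-0 library, and 5 sets hold an nrpe1 library. In these 5 sets the window deviations of the Col-0 and nrpe1 libraries from their group means correlated at 0.156, 0.284, 0.369, 0.354 and 0.111. Col-0 and nrpe1 libraries of different sets correlated at −0.245 to 0.258. Although these ranges overlap, libraries of a set were treated as pairs in the fits with a replicate block. A chi-square comparison of all library pairs within a genotype gave at least 4.45 per degree of freedom, so no library was counted as a duplicate. The labels do not say whether replicates were separate plantings; p-values measure the spread between these libraries, which may be partly technical.

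Window counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a count minimum of 10 and a total minimum of 15) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Col-0 and nrpe1 were compared within their own 11 libraries. The 4 other replicated genotypes were fitted with Col-0 and nrpe1 in 1 model of 19 libraries that shares the spread. Gene bodies were summed over windows whose midpoint lies in the gene. Gene names and positions came from a RefSeq gene table of TAIR10.1 with 37899 genes on the 5 chromosomes. Its positions match the count table: the median count over 994 genes was 1743.5 at the annotated place and between 5 and 8 when shifted by 500 bp or more. No coordinate of that table is printed. It holds no strand, so the planned upstream regions were replaced, after the data were seen, by flanks within 1 kb of either end of a gene.

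The share of a library's window counts in each class was compared between genotypes on the log2 scale by exact two-sided permutation tests, of which 27 were adjusted together by Benjamini-Hochberg. Shares of single libraries carry 95% Wilson intervals. A fold against a group without reads was computed from a floor of 3 counts over the whole group, and ratios from few counts carry 95% counting intervals. Intervals and floors cover counting error only. Shares retained in a mutant were computed within its set from counts per count of the class not transcribed by Pol V, with windows of the ribosomal DNA (rDNA) on chromosome 2 below 12 kb and on chromosome 3 left out.

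Library totals ranged from 785943 counts (drd3-3, gp5) to 6957714 (ago4, gp2). Simulated counts with the dispersion estimated per feature were used to test the procedure. Among 13646 windows tested in a simulated comparison of nrpe1 with Col-0, true log2 changes of −2 were called in 20% of cases, changes of 2 in 6%, and changes of 1 either way in 0%. For ago4 against Col-0 (30897 simulated windows) the shares were 2.5% and 12.8% at −2 and 2. For gene bodies of nrpe1 against Col-0 (7717 simulated genes) they were 48.3% and 69.4%. Changes smaller than these were mostly missed in the simulations. Each simulation changed only 200 features, far fewer than were called between Col-0 and nrpe1. The simulated shares therefore need not hold for that comparison.

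Named regions and genes followed a rule fixed before the data were examined. For nrpe1 against Col-0 these are the 10 lower and 5 higher regions with the smallest adjusted p, among regions of at least 2 neighbouring called windows and 1 per 20 kb. The 10 gene bodies lower and 5 higher in nrpe1 with the largest fitted change and a summed group mean of at least 20 counts follow, with 5 flanks, then the members past 0.05 of 7 gene lists. For other genotypes 3 regions are named each way. The values of a region are those of its window with the smallest adjusted p. Alternatives planned before the data were examined were the replicate block, DESeq2 (1.42.0) size factors and its Wald test, scaling to the class not transcribed by Pol V, stricter and looser count filters, every other window, each window capped at the level that 1 in 1000 windows of its library exceeds, windows of structural RNA genes left out, and each library left out in turn. Library totals as scaling, scaling to the class not transcribed by Pol V without rDNA (the class scaling) and shares without rDNA were added after the data were seen, and so was leaving out windows of high nrpe1 count. Planned WGBS alternatives were not run because the levels are pooled and carry no coverage. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the shares and Fisher's exact tests.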

Results

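Pol V makes non-coding transcripts that guide DNA methylation to transposons and other repeats in plants. IPARE libraries were compared between wild-type Col-0 (n = 6), nrpe1, which lacks the largest Pol V subunit and so gives the background of the antibody (n = 5), and spt5l, ago4, dms5-1 and drd3-3 (n = 2 each). The genotypes drd1, dms3, suvh2, suvh9 and the suvh2/suvh9 double mutant have 1 library each. Total window counts were 1098651 to 5647081 in Col-0 and 840847 to 2948073 in nrpe1. The NRPE1 gene itself, whose protein the antibody binds, had 0 to 39 counts per library (2.96 ± 0.69 CPM, counts scaled to the library total, in Col-0 and 2.69 in nrpe1). The position of the mutation is not given in the sources used here, so these counts check no label.

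In Col-0, RdDM windows took 33.7% ± 7.15 (SD, n = 6) of all window counts, against 4.04% ± 1.66 (n = 5) in nrpe1. Non-RdDM Pol V windows took 9.65% ± 2.07 in Col-0 and 3.29% ± 1.05 in nrpe1. Windows not transcribed by Pol V took 56.6% ± 9.14 and 92.7% ± 2.46. The log2 ratio of the RdDM share in nrpe1 to that in Col-0 was −3.13 ± 0.289 (SE). For non-RdDM windows the ratio was −1.58 ± 0.236. Both gave p = 0.00217 in exact two-sided permutation tests, the smallest p that 462 splits can give, and an adjusted p of 0.0195. Within the 5 sets that hold both genotypes the ratios were −3.13 and −1.55, with an exact p of 0.0625, the smallest that 5 pairs allow. With each window capped at the level that 1 in 1000 windows of its library exceeds, the ratios shrank to −2.71 and −0.13 (exact p = 0.00217 and 0.0238), and without rDNA to −2.47 and −0.90 (exact p = 0.00217 for both).

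A small part of the RdDM class held most of the nrpe1 background. Of its 158314 windows, 547 (0.35%) had a summed nrpe1 count of at least 20. These held 84.9% of the nrpe1 counts of the class and 7.8% of the Col-0 counts. Windows of the rDNA loci took 35.7% ± 4.85 of all counts in Col-0 and 59.9% ± 5.82 in nrpe1.

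**Figure D1:**
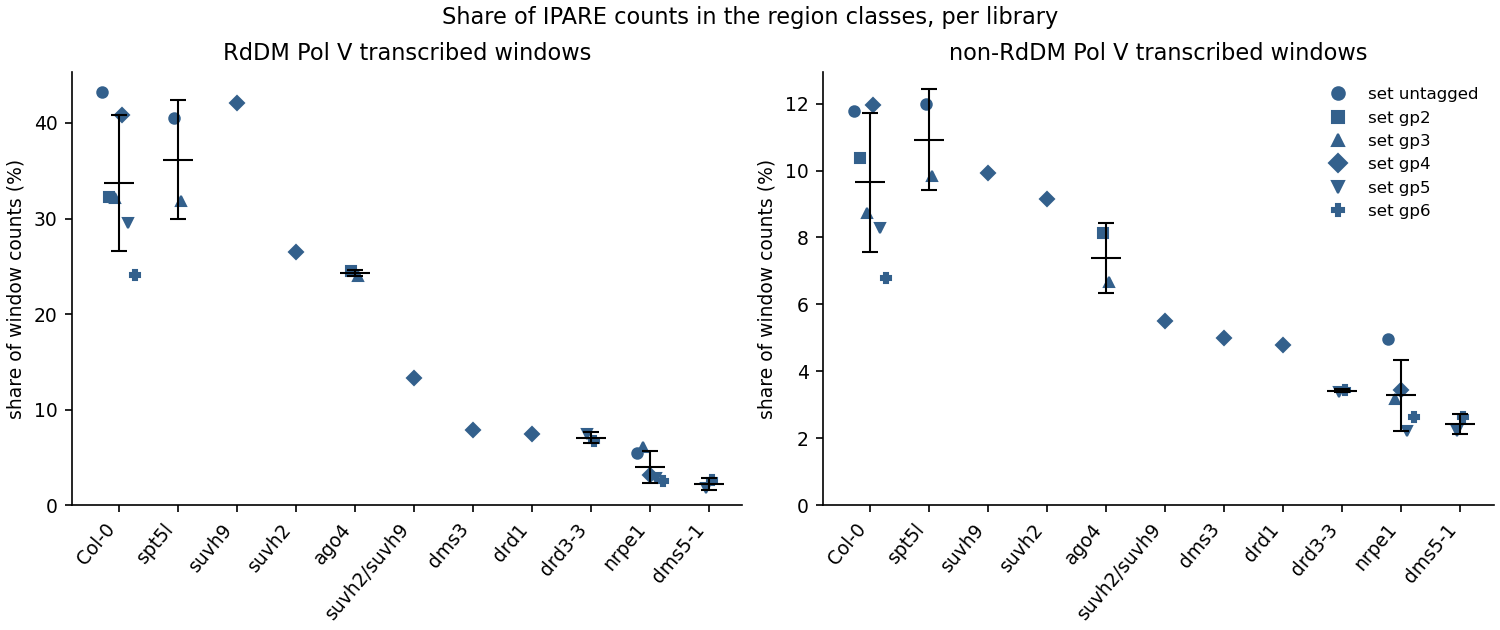
Share of window counts (%) in RdDM (left) and non-RdDM (right) Pol V transcribed windows, 1 point per library, with point shapes for the 6 sets and mean ± SD bars where a genotype has at least 2 libraries. The 6 Col-0 libraries lie between 24.1% and 43.2% for RdDM windows and the 5 nrpe1 libraries between 2.53% and 6.14%.

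The reach of Pol V transcription was also seen in libraries that the labels do not tie to the class lists. In the 3 Col-0 libraries of gp2, gp5 and gp6 together, 87.4% of RdDM windows and 54.4% of non-RdDM windows had a read, against 30.4% of windows not transcribed by Pol V. In nrpe1 of gp5 and gp6 these shares were 6.9%, 10.8% and 12.7%, at fewer counts (2341490 in all, against 6911656 in Col-0). In CPM scaled to the counts outside Pol V transcription and rDNA, RdDM windows had a mean of 7.93 in Col-0 and 0.535 in nrpe1, non-RdDM windows 1.88 and 0.358, and windows not transcribed by Pol V, rDNA included, 5.80 and 6.80. RdDM and non-RdDM windows make up 19.9% and 25.7% of all windows. No gene of the gene table covered 55.4% of RdDM windows, and pseudogenes, which in this table include transposon genes, covered 34.0%. Protein-coding genes covered 9.4% of RdDM windows, 46.7% of non-RdDM windows and 74.1% of windows not transcribed by Pol V.

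Among single windows, loss of signal in nrpe1 was the leading change. Of 15296 windows tested, 11868 were lower in nrpe1 and 2750 higher (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the RdDM windows tested, 10667 of 11119 were lower, and of the non-RdDM windows 1201 of 1792. Of the 2385 tested windows outside Pol V transcription 2217 were higher and 0 lower with edgeR, which gave 0 of them lower also at an unadjusted p under 0.05, and 50 were lower with DESeq2. The labels name the class lists for the Col-0 and nrpe1 libraries of the untagged set, gp3 and gp4, which are part of this fit. These counts by class are thus partly fixed in advance. The lower windows lay more often outside genes (89.6% of such windows called, against 47.7% elsewhere; odds ratio 9.46) and in pseudogenes (90.9% against 77.1%; odds ratio 2.97) than the other tested windows. In protein-coding genes 43.1% were lower.

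The higher calls depended on the scaling. Of the 2750 windows, 2217 of which belong to the class not transcribed by Pol V, 1 (0.04%) stayed higher when libraries were scaled to that class without rDNA, named the class scaling, 317 (11.5%) under library totals and 5 under DESeq2. Lower windows were 81.2% of all calls, 97.4% under library totals, and 12224 against 1 higher window under the class scaling. The median log2 change of all tested windows moved from −3.90 to −5.83 between TMM and the class scaling. All 11868 lower windows stayed lower under library totals, DESeq2 size factors in edgeR and the class scaling, and 11866 under DESeq2. The number of lower windows followed the number tested when a library was left out: 5900 without Col-0 of the untagged set, 6232 without Col-0 gp2, 5938 without Col-0 gp4, 18333 without nrpe1 of the untagged set, 18840 without nrpe1 gp4, 19061 without nrpe1 gp5 and 19086 without nrpe1 gp6, out of 8936 to 23810 tested. Higher windows numbered 1630 without Col-0 of the untagged set and 1652 without Col-0 gp4.

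The 10 regions named by the rule for windows lower in nrpe1 were all of the RdDM class and in or beside genes or pseudogenes of the gene table (TAIR10). They had 13.5 to 18.6 CPM in Col-0 and a single read over the 5 nrpe1 libraries, each with an adjusted p of 1.4e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On chromosome 4 from 16054351 to 16054700, in ADR1-L1, Col-0 had 14.6 ± 3.73 CPM (n = 6), 134 times the nrpe1 level (counting interval 23.8 to 5303). On chromosome 3 from 22662301 to 22662650, between AT3G61210 and SDR1, Col-0 had 18.3 ± 6.03 CPM, 178 times nrpe1 (31.7 to 7029). On chromosome 5 from 23309701 to 23310200, between AT5G08715 and AT5G57565, it had 18.6 ± 4.81 CPM. A region on chromosome 4 from 604351 to 604700 lay between UMAMIT31 and UMAMIT30, and another from 583201 to 583700 lay next to UMAMIT29. The remaining regions began on chromosome 5 at 7299751 in AT5G22044, on chromosome 2 at 8566651 beside AT2G19840, on chromosome 3 at 11134501 beside KIN11 and at 16854451 beside AT3G45840, and on chromosome 1 at 25332001 beside AT1G67580.

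The 5 regions named as higher in nrpe1 included both rDNA loci, on chromosome 3 from 14196451 to 14203550 and on chromosome 2 from 2701 to 9650. Their best windows were 1.99 times (1.98 to 2.00) and 2.08 times (2.07 to 2.10) higher in nrpe1 by pooled counts per library total. The others lay in XBAT31, in AT2G07732, and in AT2G10940. Each of the 5 lost its call under the class scaling, with log2 changes of 0.28 to 0.81. All 5 kept it under library totals, and XBAT31 also kept it under DESeq2 size factors (adjusted p = 0.0390 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and under DESeq2.

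Gene bodies followed the same direction. Their counts are 5′ ends of RNA pulled down with the antibody, so a lower value in nrpe1 does not measure lower expression of the gene. Of 8476 tested, 3696 were lower in nrpe1 and 147 higher (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the set as a replicate block 3790 were lower and 770 higher, so that lower calls fell from 96.2% to 83.1% of all calls. Under the class scaling edgeR called 4012 gene bodies lower and 0 higher, with 4227 at an unadjusted p under 0.05 either way. Leaving out single libraries moved the number of higher gene bodies between 88 (without Col-0 gp5) and 1202 (without nrpe1 gp6). It was 328 without Col-0 of the untagged set, 580 without Col-0 gp2, 756 without Col-0 gp3, 606 without Col-0 gp4, 844 without nrpe1 of the untagged set, 859 without nrpe1 gp3, 1147 without nrpe1 gp4 and 995 without nrpe1 gp5.

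The 10 gene bodies with the largest fall had no read in any nrpe1 library. AT5G51650, a protein-coding gene, had 32.8 ± 8.65 CPM in Col-0 (n = 6) and was at least 101-fold lower in nrpe1. The pseudogene AT1G31030 had 31.6 ± 4.24 CPM and was at least 96.4-fold lower. BGLU13, a beta-glucosidase gene, was at least 91.5-fold lower, and SUC7, a sucrose transporter gene, at least 76.9-fold lower. The remaining 6 were AT2G14470, AT5G28730, AT5G24775, AT2G14455, AT5G44830 and AT2G22350, with bounds of 83.0-fold to 92.7-fold. Among the higher gene bodies the rule named TRX5, AT5G42530, WRKY70, AT3G49910 and AT3G01690. WRKY70, a transcription factor of defence signalling, had 5.02 ± 2.12 CPM in Col-0 and 17.5 ± 7.18 in nrpe1, and none of the 5 kept its call under the class scaling.

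Pulled-down RNA over transposons fell as a group. All 11 measured members of the list of transposons known from RdDM work were lower in nrpe1, with a median log2 change of −4.23, and all 11 also when adjusted over the list alone. ONSEN, a heat-responsive retrotransposon family, is present in 8 near-identical copies, so reads may be shared among them and values of single copies are uncertain. ONSEN7 had 60.4 ± 10.6 CPM in Col-0 and 3.28 ± 2.09 in nrpe1, and ONSEN4, with the smallest ratio, 27.2 ± 10.9 against 6.99 ± 2.69. The retrotransposon EVD had 9.02 ± 3.06 CPM in Col-0 and no nrpe1 read, at least 26.6-fold lower. ATMU1 was 98.5 times lower (27.1 to 816) from 2 nrpe1 counts, and ATGP1 19.5 times lower (7.47 to 72.3).

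Of the genes with a known RdDM target sequence, 4 of 5 measured were lower, also when adjusted over the list alone. FWA, a homeobox gene whose promoter repeats are methylated, had 20.9 ± 8.51 CPM in Col-0 and 33.4 times less in nrpe1 (15.2 to 91.5). QQS was 68.9 times lower (18.9 to 572) and SDC 24.9 times lower (8.38 to 122). ROS1, a DNA demethylase gene that carries a methylation-sensing sequence, had 38.2 ± 15.8 CPM in Col-0 and 29.9 times less in nrpe1 (17.0 to 58.0). ALN did not pass, with a log2 change of −0.58 ± 0.445 (SE).

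Among genes of the RdDM pathway, 2 of 5 measured were lower and 3 were not called, also when adjusted over the list alone. With the loose filter 20 members were tested, of which 4 were lower and 0 higher. Lower calls were common among all gene bodies tested, so this is no trait of the pathway. Pulled-down RNA over SUVH2 and SUVH9, which bring Pol V to methylated DNA, was 20.1 times (10.8 to 42.2) and 6.39 times (3.91 to 11.2) lower in nrpe1. SPT5L, MORC1 and IDN2 had log2 changes of −0.69, −0.32 and 0.66. In the list for maintenance and removal of DNA methylation, 2 of 5 were lower, ROS1 and IBM1, a histone demethylase gene (3.58 times, 2.79 to 4.67), with the same count adjusted over the list alone. Under the class scaling 4 of 5 were lower, and 4 of 5 with DESeq2.

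Abundant Pol II transcripts served as the background lists. Of 21 photosynthesis genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, also 0 when adjusted over the list alone and 0 with DESeq2, while 5 had an unadjusted p under 0.05. Their median log2 change was 0.81, and 0.19 under the class scaling. RBCS1A, the small subunit of Rubisco, had 134 ± 78.1 CPM in Col-0 and 251 in nrpe1 (adjusted p = 0.107 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the set as a replicate block all 21 were higher. Of 12 housekeeping genes SAND was lower, and GAPC1 and EF1A-A1 were higher, of which 1 lower and 1 higher were called when adjusted over the list alone. With the block 4 were higher, and under the class scaling the median log2 change of this list was −0.04 and none was higher. Of 7 stress genes edgeR called 0, also 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05, while 1 was lower and 2 higher with the block and 1 lower with DESeq2.

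Gene flanks showed the same loss, in a test added after the data were seen. Of 14088 tested, 8954 were lower in nrpe1 and 3303 higher, and under library totals 10590 were lower and 271 higher. Those named by the rule had no nrpe1 read: the flanks of AT2G09015, AT2G09020 and AT1G06147 (long non-coding RNA genes), AT1G09035, and CBL8, a calcium sensor gene. They were at least 237-fold, 187-fold, 162-fold, 141-fold and 136-fold lower, in that order. All 5 measured flanks of the known RdDM targets were lower, and 8 of 10 in the RdDM pathway, such as those of DCL3 (26.4 ± 7.54 CPM in Col-0, 2 nrpe1 counts) and HEN1 (23.4 ± 3.18 CPM, 1 nrpe1 count). With the set as a replicate block 4 of 5 and 7 of 10 were lower. For the other lists 3 of 4 (maintenance and removal), 9 of 11 (transposons), 3 of 9 (photosynthesis), 1 of 5 (housekeeping) and 1 of 1 (stress) were lower, and 1, 1, 6, 3 and 0 were higher, of which the block changed only the 3 housekeeping flanks, to 1. Under library totals, where the median log2 change of all flanks moved from −2.34 to −4.33, these higher calls ended. The median of the photosynthesis flanks moved from 2.45 to 0.59. That of the housekeeping flanks turned from 1.32 to −0.865, so its direction depends on the scaling. DESeq2 called 4 photosynthesis flanks higher. Under library totals 10 of 11 transposons, 10 of 10 pathway members and 2 of 5 housekeeping genes were lower. With the loose filter 19 pathway flanks were tested, of which 9 were lower and 3 higher. Their median log2 change was −1.07, instead of −3.52 over the 10. All 7 flanks of known RdDM targets tested with that filter were lower.

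DNA methylation was compared between Col-0 and nrpe1 on the authors' averages. In RdDM windows mean CHH methylation was 9.78% in Col-0 and 6.95% in nrpe1, and the medians were 8.53% and 6.63%. Non-RdDM windows had 0.14% and 0.10%. The class lists set RdDM targets apart from other Pol V windows, so the gap between the classes may be built into the lists. When RdDM windows were put into 4 equal groups by Col-0 read count, the difference between Col-0 and nrpe1 lay in the upper groups. It was 8.27% in Col-0 and 6.76% in nrpe1 in the group with a mean of 19.9 reads, and 13.1% and 3.49% in that with 137 reads. The lower groups had 8.50% and 8.60%, and 9.28% and 8.93%, in Col-0 and nrpe1. The averages carry no replicate spread, so none of these differences was tested.

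**Figure D2:**
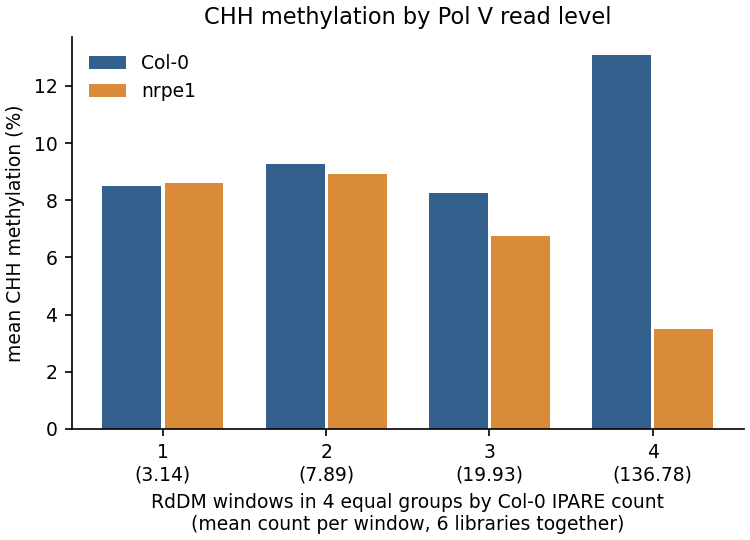
Mean CHH methylation (%, the authors' averages, Col-0 and nrpe1 bars) of RdDM windows in 4 equal groups by their Col-0 IPARE count, with the mean count per window over the 6 libraries in brackets. In the highest group the level is 13.1% in Col-0 and 3.49% in nrpe1, and no error bar can be drawn because the values are pooled.

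SPT5L is an elongation factor-like partner of Pol V. Loss of SPT5L left most Pol V signal in place: RdDM windows took 36.2% ± 6.19 (n = 2) of counts in spt5l, a log2 ratio to Col-0 of 0.12 (exact permutation p = 0.75). Its sign is not settled, since it was −0.054 when paired by set, −0.074 with capped windows, −0.007 without rDNA and down to −0.057 with 1 library left out. Within its sets, scaled to the class not transcribed by Pol V, the RdDM signal was 68.4% and 81.7% of Col-0, or 66.7% and 78.8% above nrpe1. Against nrpe1 the log2 ratio was 3.25, with an exact permutation p of 0.0476, the smallest of 21 splits (adjusted 0.0857). In the window test 1402 of 36843 were lower and 266 higher than Col-0 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Higher windows numbered 167 with the replicate block, 144 with DESeq2 size factors, 123 under the class scaling and 87 with DESeq2. The count of all calls rests on both libraries: 43 windows were called without spt5l of the untagged set, 93 without spt5l gp3 and 3055 without Col-0 gp3. Against nrpe1, 27063 windows were higher and 3274 lower, and 95 lower under the class scaling.

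Single places in spt5l departed from that. On chromosome 4 from 17511451 to 17512100, between HCF164 and AT4G37210, Col-0 had 14.1 ± 4.46 CPM and spt5l no read, at least 51.6-fold lower. Beside AGL8 on chromosome 5 from 24509851 spt5l was at least 44.8-fold lower, and beside AT3G44605 on chromosome 3 from 16186501 it was 117 times lower (20.8 to 4640). Within ASY2, a meiotic gene copy, on chromosome 4 from 15547951 to 15548900, spt5l had 15.1 ± 2.51 CPM, 153 times Col-0 (41.6 to 1272). Between the pseudogenes AT3G30620 and AT3G30630 on chromosome 3 from 12191851 it had 70.2 ± 7.5 CPM, 61.6 times Col-0 (40.8 to 97.8). A further region began on chromosome 1 at 18078451 beside AT1G48870 (99.4 times, 38.2 to 368). The regions named against nrpe1 as higher began on chromosome 3 at 3538651, on chromosome 2 at 1110751 and on chromosome 5 at 23240401 in ZTL, a photoreceptor gene of the clock. Those named as lower lay in AT5G58720, AT3G16370 and CP12-1.

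AGO4 is the Argonaute that carries the small RNAs of the pathway. RdDM windows took 24.3% ± 0.32 (n = 2) of counts in ago4, a log2 ratio to Col-0 of −0.45 (exact permutation p = 0.107). It was −0.23 with capped windows (exact p = 0.0357) and −0.23 without rDNA (exact p = 0.214). Within its sets the scaled RdDM signal was 74.7% and 64.3% of Col-0, the latter 58.5% above nrpe1. Against nrpe1 the log2 ratio was 2.68, with an exact permutation p of 0.0476, the smallest of 21 splits (adjusted 0.0857). Of 36843 windows 3144 were lower than Col-0 and 685 higher (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lower calls were 82.1% of all, 95.2% with DESeq2, 93.5% with the class scaling and 45.4% with the loose filter. The number of calls was 1102 without ago4 gp2 and 6730 without Col-0 gp3. Against nrpe1 24918 windows were higher and 2033 lower, and 227 lower under the class scaling.

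The ago4 changes gathered in blocks. On chromosome 2 between 4 and 12 Mb, a part picked after the values were seen, 29.5% of 3151 tested Pol V class windows were lower than Col-0, against 7.80% of 28322 elsewhere. Further peaks lay on chromosome 1 at 8 Mb (38.2%) and on chromosome 5 at 26 Mb (40.5%). All 6 regions named by the rule lay on chromosome 2. In AT2G14870, from 6391051 to 6392150, Col-0 had 20.6 ± 5.65 CPM and ago4 no read, at least 84.2-fold lower. AT2G15800, from 6880951, was at least 79.2-fold lower and AT2G21465, from 9194701, at least 41.2-fold lower. Beside FUT4, from 6711751 to 6712250, ago4 had 22.2 ± 0.345 CPM, 224 times Col-0 (61.5 to 1864), and no read was found in nrpe1. The other higher regions began at 7525501 (404 times, 71.8 to 16040) and 9457351 (295 times, 52.2 to 11730). Against nrpe1 the named higher regions began at 7525501 and 6711751 on chromosome 2 and at 9571801 on chromosome 1, and the lower ones lay in AT2G11240, CCR1 and NAD-ME1.

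**Figure D3:**
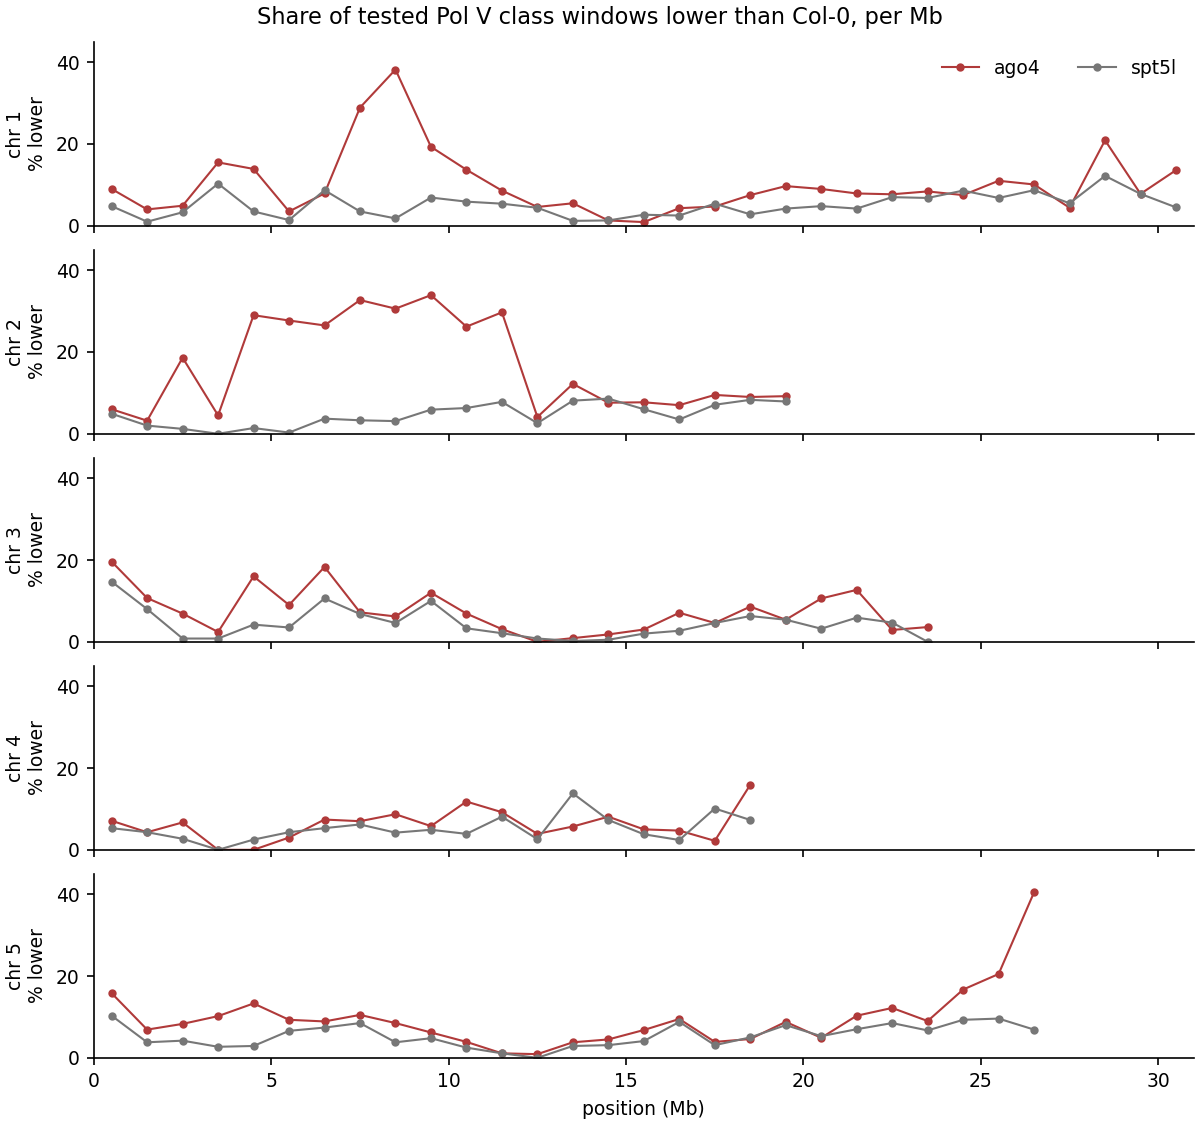
Percentage of tested RdDM and non-RdDM windows called lower than Col-0 in each Mb (x axis, position in Mb; 1 panel per chromosome), for ago4 and spt5l, over bins with at least 20 tested windows. The ago4 line lies between 26.2% and 33.9% in each Mb of chromosome 2 from 4 to 12 Mb.

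The labels name dms5-1 and drd3-3 only by allele, so the values below do not tell whether they alter NRPE1 or another gene. In dms5-1 RdDM windows took 2.22% ± 0.65 (n = 2) of counts, and in drd3-3 7.09% ± 0.57 (n = 2), with log2 ratios to Col-0 of −3.93 and −2.22. Each had an exact permutation p of 0.0357, the smallest of 28 splits, and an adjusted p of 0.0857, so neither passed. With capped windows these ratios were −2.85 and −1.16, and without rDNA −3.09 and −1.56. Against nrpe1 the ratios were −0.80 and 0.90 (exact permutation p = 0.143 for both). Within its sets drd3-3 kept 21.0% and 25.2% of the scaled Col-0 RdDM signal, or 15.1% and 17.6% above nrpe1. The dms5-1 values were −1.7% and 0.3% above nrpe1. With capped windows drd3-3 was above nrpe1 by a log2 ratio of 1.55, with an exact permutation p of 0.0476.

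In the window test dms5-1 had 28241 of 36843 windows lower than Col-0 and 820 higher. The higher ones depended on the scaling, with 478 under library totals, 127 with DESeq2 size factors, 113 under the class scaling and 109 with DESeq2. None differed from nrpe1, with 0 calls by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1400 windows at an unadjusted p under 0.05, and 8 calls by DESeq2. For drd3-3, 15127 were lower than Col-0 and 2002 higher. That count did not hold without either library, with 155 windows called without drd3-3 gp5 and 0 without drd3-3 gp6. It was 8424 with the replicate block and 27654 with DESeq2 size factors, and lower calls were 88.3% of all, 78.8% with the block, 98.8% with these size factors and 98.9% with the class scaling. Against nrpe1, 893 windows were higher in drd3-3 and 1 lower, of which 808 were RdDM windows. Between 336 (without drd3-3 gp5) and 1534 (without nrpe1 of the untagged set) were called in all when a library was left out, with 523 without drd3-3 gp6, 494 without nrpe1 gp3 and 483 without nrpe1 gp4. Compared directly, 147 windows were higher in drd3-3 than in dms5-1 and 0 lower, 458 and 0 with the block, and 4845 had an unadjusted p under 0.05.

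Among the named regions, dms5-1 had no read in AT1G55535 and LNO1 on chromosome 1 from 20733901 to 20734550, where Col-0 had 33.1 ± 6.45 CPM, at least 24.7-fold lower. It was also without reads beside STY17 on chromosome 4 from 16951351 (at least 33.1-fold) and beside AT5G25451 on chromosome 5 from 8860651 (at least 25.9-fold). Higher regions lay in ADC2, RCA and AT1G05135, and kept their calls under each of these scalings. For drd3-3 the lower regions lay beside GYRB3 on chromosome 5 from 1115401 (at least 11.3-fold), beside AT5G49210 on chromosome 5 from 19952101 (at least 19.2-fold) and beside B160 on chromosome 4 from 11415601 (at least 20.5-fold), and each lost its call when either drd3-3 library was left out. The higher ones lay beside PTR3 and in GAPA and RCA, and lost their calls without drd3-3 gp6. Against nrpe1, drd3-3 had 71.3 ± 14.5 CPM in ATMYC1 on chromosome 4 from 216601, 164 times nrpe1 (62.3 to 610). The others lay beside AT3G33565 on chromosome 3 from 14065051 (45 times, 16.0 to 175) and beside AT2G05820 on chromosome 2 from 2223451 (at least 40.0-fold).

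The remaining mutants had 1 library each, all of gp4, so their differences have no replicate check. In drd1, which lacks a chromatin remodeller needed by Pol V, RdDM windows took 7.5% of counts (95% Wilson interval 7.47% to 7.53%), and in dms3 7.88% (7.85% to 7.92%). Col-0 of the same set had 40.9% and nrpe1 3.18%. The scaled RdDM signal was 7.5% of Col-0 in drd1, 9.0% in dms3, 40.0% in suvh2, 101% in suvh9 and 15% in suvh2/suvh9, against 3.8% in nrpe1. Above nrpe1 these were 3.8%, 5.4%, 37.6%, 101% and 11.6%. Without windows of high nrpe1 count, an alternative chosen after the data were seen, the signal was 3.36%, 4.37%, 29.2%, 100% and 11.2% of Col-0, against 0.38% in nrpe1. SUVH2 and SUVH9 are related proteins that bind methylated DNA, and the double mutant had less signal than either single mutant. For non-RdDM windows the values were 16.4% in drd1, 19.5% in dms3, 47.1% in suvh2, 81.5% in suvh9 and 21.1% in suvh2/suvh9, against 14.2% in nrpe1. Without windows of high nrpe1 count they were 10.7%, 13.3%, 37.2%, 80.6% and 16.7% in the same order, against 8.64% in nrpe1. The windows left out were picked by their nrpe1 counts, so the nrpe1 values of both classes fall by construction under this alternative. How far a mutant lies above nrpe1 cannot be judged from it.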

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

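The tests of the nrpe1 scaling, of swaps within sets, of an even ago4 effect, of merged loci, and of drd3-3 scaling, a shared defect and signal in other mutants were chosen only after those results were seen; the tests of other splits, of foreign DNA, of carry-over and of CHH level were set before.

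Among 106 groups with a spread, 19 had a library far from the others of its genotype by Dixon's test, where chance gives about 5.3. The rDNA share of nrpe1 in the untagged set was 49.6%, and the nearest of the other nrpe1 libraries had 61.3%. The 10 named regions lower in nrpe1 stand out only because their single nrpe1 read fell into 1 library, at 0.582 CPM in gp4 for 3 of them and 0.339 CPM in gp3 for 7. QQS likewise had its nrpe1 reads in gp5 alone (1.33 CPM).

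The rDNA window on chromosome 2 from 9151 had 9851 CPM in Col-0 gp3, against 6531 in the next library. AT5G42530 was highest in gp4 in both genotypes, with 22.3 CPM in Col-0 (next 9.32) and 82.6 in nrpe1 (next 21.3). GAPC1 had 15.7 CPM in Col-0 gp4 (next 5.64). ONSEN3 and ONSEN8 had 9.89 and 15.1 CPM in nrpe1 gp4 (next 2.38 and 4.76), and ONSEN6 had 3.35 CPM in nrpe1 of the untagged set (next 0.339).

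The loss of windows in nrpe1 was set against chance. Of 50 drawn splits of the 11 libraries, only the real split, 1 of 50, called as many windows (14618, of which 11868 lower, against at most 116), gene bodies (3843 against at most 0) or flanks (12257 against at most 3). This argues against chance for each count but does not exclude it, since 1 of 50 is the smallest share these splits can give. Of the 32 splits that swap Col-0 and nrpe1 within the 5 sets or leave them, also only the real one did, against at most 116 windows, 0 gene bodies and 1312 flanks. That is a share of 0.0312, the smallest these swaps can give. Of the windows called higher in nrpe1, 0.04% stayed higher when libraries were scaled to the class not transcribed by Pol V without rDNA, but 2217 of the 2750 belong to that class, so this test is void. Of the scalings that rest on no class, library totals kept 11.5% of them and DESeq2 size factors 0.15%. The TMM factors of the nrpe1 libraries ran from 0.215 to 1.04. The median log2 change of the windows called higher was 2.23 under TMM, 0.69 under library totals and 0.16 under DESeq2 size factors. The size of the rise thus depended on the scaling, and whether a smaller rise is real cannot be told.

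The block of lower windows in ago4 on chromosome 2 argues against 1 effect of the same strength everywhere: the share of lower Pol V class windows was 3.78 times that elsewhere, 4.38 times with the replicate block and 0.857 times in spt5l. The part was picked for its high share, but over all stretches of that length no permutation of blocks along the genome passed 1.88 (permutation p = 0.000999, the smallest it can give), and the highest stretch in spt5l was 1.95, also above chance (permutation p = 0.00200). Pol V class windows called higher in ago4, looked at later, were also more frequent in this part. They were 2.48% of those tested there and 1.3% elsewhere, and 1.81% and 0.79% with the replicate block. DNA of another strain around the ago4 allele may account for the block, and windows outside Pol V transcription, which would then change too, were called either way in 6.98% of cases there and 4.42% elsewhere (Fisher's exact two-sided p = 0.0643), with p = 0.0151 under the block, 0.0310 under library totals and 0.00480 under the class scaling. These p-values may be too small because neighbouring windows share reads; with windows within 1 kb merged, 12 of 113 loci were called there and 115 of 2193 elsewhere (Fisher's exact p = 0.0304), with p = 0.0833 under the block, 0.0363 under library totals and 0.00485 under the class scaling. Lower calls alone, looked at later, were 3 loci there and 1 elsewhere (Fisher's exact p = 4.4e-04), 2 and 3 under the block (p = 0.0216), but the test set before missed its threshold, so this stays open, and a local loss of Pol V signal through AGO4 itself was not tested.

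Of the 893 windows higher in drd3-3 than in nrpe1, at least 830 (92.95%) stayed higher under each of 4 other scalings, and 828 with DESeq2, which argues against scaling as their source. Carry-over of Col-0 material would keep the same share everywhere. The kept share differed 1.90 times between 4 equal groups of windows by CHH level in gp6 and 3.14 times in gp5, with the same group highest. Without windows of high nrpe1 count it differed 1.76 and 2.71 times. That group was also the highest in drd1, dms3 and suvh2/suvh9 of gp4, so it is not particular to drd3-3. There dms5-1 of gp5 had −8.89% above nrpe1 over all windows and 0.44% without windows of high nrpe1 count. Subtracting nrpe1 over all windows is thus uncertain in that group. In dms5-1, from the same sets, edgeR called 0 windows higher than nrpe1 (1400 at an unadjusted p under 0.05 either way, 8 calls with DESeq2), which argues against a defect shared by both sets. In libraries of gp4, 814 of these windows had a median of 13.0% of the Col-0 signal in drd1 and 13.8% in dms3, against 0.0% in other windows of like Col-0 count. The summed signal was 18.6% against 14.5% in drd1 and 20.1% against 17.7% in dms3. In nrpe1 of gp4 it was 0.6% against 12.7%, so the sums hold unlike backgrounds. Low nrpe1 counts helped to pick these windows, so that difference is partly fixed in advance. The median in suvh9 was lower, at 79.8% against 96.1%. The same windows may thus keep signal in several mutants. Partial Pol V activity in drd3-3 is a hypothesis drawn from these libraries and was not tested.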

How the results depend on the processing

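The alternatives by library totals, by the class not transcribed by Pol V without rDNA, by shares without rDNA, by leaving out windows of high nrpe1 count and by windows of like Col-0 count, and the flanks themselves, were chosen after seeing the data. Of the values that answer a comparison, 360 were the same under an alternative. They kept direction and side of the threshold, or a number of calls stayed within a fixed ratio of the first. Values that passed in neither fit are among them. Of the others 77 fell below the threshold or to fewer calls, and 34 rose above it or to more calls. A further 20 moved by more than their interval and 7 reversed. For single named regions and genes and the share not transcribed by Pol V these were 1645 the same, 57 weaker, 1 stronger and 4 reversed. Except where a cause is named, the cause was not tested. The planned upstream regions, WGBS coverage minimums and WGBS samples left out were not run, because the gene table holds no strand and the levels are pooled without coverage. Where a library left out leaves 1 in a genotype, that one is assumed to vary like the other groups. From 8936 to 23810 windows passed the count filter as single libraries were left out, and windows below it were not tested.

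Every other window lowers the counts by construction, and why the counts moved under the other filters was not tested. With the loose filter 96342 windows were lower and 12331 higher in nrpe1 than in Col-0; 3280 were called in spt5l, 9647 in ago4, 82005 in spt5l against nrpe1, 79855 in ago4 against nrpe1 and 41 in dms5-1 against nrpe1. The strict filter left 10664 calls in drd3-3. With every other window 5873 were lower and 1371 higher in nrpe1, and 819 were called in spt5l, 1896 in ago4, 14490 in dms5-1, 8542 in drd3-3, 15102 in spt5l against nrpe1, 13449 in ago4 against nrpe1 and 452 in drd3-3 against nrpe1. The loose filter gave 8843 lower and 645 higher gene bodies and 5914 higher flanks.

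The higher calls in nrpe1 changed with the scaling. Windows higher in nrpe1 numbered 317 under library totals, 4 with DESeq2 size factors in edgeR, 5 with DESeq2, 0 when scaled to the class not transcribed by Pol V and 1 when that class was taken without rDNA. Higher gene bodies numbered 228 under library totals, 73 with DESeq2 size factors and 0 without rDNA. Higher flanks numbered 271, 1178 and 3 in the same order, and 1444 with DESeq2. Calls in drd3-3 were 27654 with DESeq2 size factors, 27971 when scaled to the class and 27367 without rDNA. DESeq2 called 8 windows in dms5-1 against nrpe1.

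With each library left out in turn, windows lower in nrpe1 ranged from 5900 to 19086 and higher ones from 1630 to 3687. Calls ranged from 43 to 3055 in spt5l, from 1102 to 6730 in ago4, from 0 to 19386 in drd3-3 and from 336 to 1534 in drd3-3 against nrpe1. Higher gene bodies ranged from 88 to 1202. The log2 ratio of RdDM shares ranged from −0.057 to 0.294 in spt5l against Col-0, from 3.07 to 3.42 in spt5l and from 2.54 to 2.85 in ago4 against nrpe1. For non-RdDM shares it ranged from 1.64 to 1.94, from 1.07 to 1.38, and from −0.017 to 0.275 in spt5l, ago4 and drd3-3 against nrpe1. With 1 of the 5 nrpe1 libraries left out, the smallest exact permutation p for spt5l and ago4 is 0.0667, so none of these can pass. The log2 ratio of the share not transcribed by Pol V in spt5l to Col-0 ranged from −0.239 to 0.059.

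Sets were treated as pairs in the fits with a replicate block. These called 8424 windows in drd3-3 and 770 higher gene bodies, and 167 windows higher in spt5l instead of 266. Windows higher in drd3-3 than in dms5-1 rose from 147 to 458. Called photosynthesis gene bodies rose from 0 to 21, called stress gene bodies from 0 to 3 and higher housekeeping gene bodies from 2 to 4. Paired by set, the log2 ratios of RdDM and non-RdDM shares were −3.13 and −1.55 in nrpe1, −3.62 and −1.63 in dms5-1, −1.92 and −1.13 in drd3-3 and 2.62 and 1.45 in spt5l against nrpe1, all with too few pairs for an exact p under 0.05. In spt5l against Col-0 the paired ratios were −0.054 for RdDM windows and 0.029 for windows not transcribed by Pol V, both of the opposite sign to the unpaired ones.

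Libraries that the labels do not tie to the class lists gave log2 ratios of RdDM and non-RdDM shares of −3.41 and −1.79 in nrpe1, −3.71 and −1.79 in dms5-1, −2.01 and −1.29 in drd3-3, 3.74 and 2.17 in spt5l against nrpe1 and 3.18 and 1.60 in ago4 against nrpe1. With so few libraries the exact permutation p cannot be under 0.1, or under 0.333 against nrpe1.

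With each window capped, the RdDM ratio was −0.074 in spt5l and −0.23 in ago4 against Col-0, and 1.55 in drd3-3 against nrpe1; the non-RdDM ratio was −0.122 in dms5-1 against Col-0, and 0.003 in ago4, 0.01 in dms5-1 and −0.092 in drd3-3 against nrpe1. The share not transcribed by Pol V in spt5l then had a ratio of 0.206, and without rDNA 0.041, where the RdDM ratio was −0.007. The RdDM and non-RdDM shares of the single libraries rise under both settings; without rDNA the total is smaller by construction, and why they rise when capped was not tested. Capped, they were 16.6% and 16.0% in drd1, 17.8% and 16.8% in dms3, 44.5% and 18.3% in suvh2, 66.1% and 16.2% in suvh9 and 33.6% and 16.5% in suvh2/suvh9. Without rDNA they were 14.5% and 9.3%, 16.6% and 10.5%, 42.9% and 14.8%, 61.5% and 14.6%, and 24.7% and 10.2% in the same order.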

Other observations

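The test by CHH level was set before its result was seen, and the remaining values were picked after they were seen.

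Some Pol V signals did not follow the others. In the non-RdDM region of ATMYC1 on chromosome 4 from 216601, the best window had 29.6 ± 5.85 CPM in Col-0 (n = 6) and 0.705 ± 0.981 in nrpe1 (n = 5). It had 0.969 CPM in dms5-1, 33.3 in spt5l and 52.0 in ago4, and 71.3 in drd3-3, 159 in drd1, 187 in dms3, 156 in suvh2/suvh9, 49.9 in suvh2 and 15.6 in suvh9. The single libraries have no replicate check, and these differences from Col-0 were not tested apart from the window test of the replicated genotypes. The region between AT3G33565 and AT3G33555 on chromosome 3 was similar, with 3.6 CPM in Col-0, 0.451 in nrpe1, 24.0 in drd1 and 20.3 in dms3. CPM rise in libraries that lost other signal: scaled to counts outside Pol V transcription and rDNA, in an alternative chosen after seeing the data, the window in ATMYC1 had 1.81 times the Col-0 level of the set in drd1, 2.41 in dms3, 1.98 in suvh2/suvh9 and 0.847 in suvh2, instead of 4.40, 5.16, 4.30 and 1.38. The other had 2.70 times in drd1 and 2.59 in dms3 instead of 6.56 and 5.54, over 10 Col-0 counts.

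Signal kept in suvh2/suvh9 was compared between 4 equal groups of RdDM windows by CHH level. From the lowest to the highest level the kept shares were 9.17%, 13.0%, 16.9% and 12.2%. They differed 1.32 times between the lowest and the highest group, the comparison set before, and 1.84 times between the largest and the smallest share (1.64 times without windows of high nrpe1 count). With 1 library no spread is known against which to judge it.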
